A study of Mus musculus with 24 samples.

How the data were processed

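Epididymal white fat was collected at 19 weeks of age from male CD-1 mice, an outbred stock, whose mothers had received bisphenol A (BPA) by mouth at 500 ug per kg per day, or the corn oil vehicle, from gestational day 9 to 18. The offspring ate a standard chow with 4% fat. Per the labels' protocols, DNA and RNA were taken from the same tissue. Sonicated DNA was enriched for methylated fragments with the methyl-CpG binding domain of MBD2 (MBD-seq), RNA was depleted of ribosomal RNA, and both kinds of library were made with SOLiD kits. The 24 libraries come from 12 animals, each with 1 MBD and 1 RNA library, in 4 groups of 6. Groups and replicate numbers were taken from the sample descriptions, and columns were joined to samples by the animal identifier in the titles. The labels do not say which animals were littermates, so p-values treat the 6 animals of a group as independent.

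The RNA values are the authors' normalized read counts per gene, a signal on a common library size and not raw counts. The authors used the mm9 build and edgeR, per the submitters' processing notes. The version of edgeR the authors used, the aligner and the gene annotation are not given in the sources used here. The deposited RNA signal sums to between 9628801 and 11582945 per library because it was rescaled, so sequencing depth is unknown, and whole reads could not be recovered from the low values. A panel of 13 genes stands above the full table. Of these rows 12 repeat rows of the table and were dropped, and the remaining one, Itgax, was kept, which gave 20624 genes. In 25 rows the symbol had been turned into a calendar date, and 512 rows carry a name marking a duplicate. These rows were tested and are not named.

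The MBD values are the authors' score per 100 bp window, between 0 and 1, for 1000 windows on 20 chromosomes of mm9. What the deposited score measures, how the windows were chosen and the coverage behind each value are not given in the sources used here, so no coverage filter or interval for counting error could be set. A count-like unit had been assumed when the tests were fixed. Because the score is bounded and holds many zeros, the differences were tested on the score itself, without a logarithm or pseudocount. No mm9 gene annotation was used here, so windows are given by position only, they were not assigned to genes, and the test of methylation against RNA in the same animals was not run.

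The authors also deposited p-values and a linear fold for their own comparison, in 4 smaller tables that narrow the gene list in steps, the last of them identical to the one before it. These were described and checked against the full table, with no new test of those groups other than counts over other splits of the libraries. The 12 per-sample columns of that identical last table were not used.

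BPA was compared with vehicle over the 12 RNA libraries with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1). Genes needed a value of at least 10 in at least 6 libraries, which left 12528. Fold changes are on this log2(value + 1) scale, which understates the change of genes with low values. P-values are two-sided with Benjamini-Hochberg adjustment at 0.05. Gene lists, 25 of them, were fixed before the data were examined: white adipocyte identity, fatty acid and triglyceride synthesis, cholesterol synthesis, brown and beige fat, oxidative phosphorylation, fatty acid oxidation, insulin signalling, macrophage, inflammatory cytokines and acute phase, interferon response, T and B lymphocyte, endothelium, fibroblast and extracellular matrix, mesothelium, smooth muscle, skeletal muscle, erythroid, epididymal epithelium, testis germ cells, nuclear receptors and steroid metabolism, DNA methylation machinery, imprinted genes, circadian clock, immediate early and heat shock, and cell cycle. Of their 468 members 457 were found in the table by symbol, or by an older symbol in the RefSeq gene table of GRCm38, and 363 passed the filter. Lists were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. A further 4 marker lists (duct epithelium, ciliated cells, kidney tubule and hepatocyte) were written after many of their members' values had been seen. The genes Cubn, Amn, Aqp1, Dab2, Tekt2, Tppp3 and Slc5a2, at first left out of these lists after their values had been seen, were put back. For the test of duct against cilia transcripts, 7 ciliated cell genes whose own values had not been looked at when the list was written were used alone, although the correlation of the whole ciliated list was known by then. The single gene Fggy, known as the subject of the study, was also tested by exact permutation over all assignments of the libraries to groups of 6. MBD windows were tested with limma in the same way.

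The rule for named genes was fixed before the data were examined. It takes up to 12 genes per direction past the adjusted threshold, or the 5 with the smallest p per direction where fewer pass. In each list it takes every member past the threshold over all genes or over the list alone, otherwise up to 3 members with the smallest p. It adds Fggy, the 6 MBD windows with the smallest p where no window separates the groups, and the 8 genes per direction with the largest fold in the authors' last table. Some genes that the rule picks are left unnamed. Genes named outside this rule are said to have been chosen after their values were seen.

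The steps were tested on simulated data. Counts were drawn for the 12528 genes from the real means and spreads, treating genes as independent, and the RNA test recovered 37.3% of the genes changed 1.5-fold, 70.1% of those changed 2-fold and 92.4% of those changed 4-fold, with 10 false calls. Camera called the 1 shifted list and 1 of 20 unshifted lists. For this test the group means had been removed from the real values, so unshifted genes had a difference of exactly 0. The lists were random genes. These counts therefore give no error rate of camera for the real lists. In the 1000 MBD windows, 94 of 100 windows shifted by a score of 0.4 were called, with 0 false calls. Here too the group means had been removed, so an unshifted window had no difference to call and the 0 gives no error rate. The shifted windows carried no sampling error in their group means. The shift also exceeds the largest difference of the 6 windows with the smallest p (0.343). The 94 therefore does not show how often differences of that size would be called. Alternatives covered the pseudocount, the filter on low values, the scaling, the test, the replicate number as a block and each library left out in turn. After seeing the data, fits without the libraries highest in duct epithelium markers, with those markers as a covariate, and with other scalings of the MBD scores were added.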

Results

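Gene expression and DNA methylation were measured in epididymal white fat of 12 adult male mice, 6 exposed before birth to BPA, an estrogen-like plasticizer, and 6 whose mothers received corn oil. Each animal gave 1 RNA library and 1 MBD library, in which DNA bound by a methyl-CpG binding protein is sequenced. The RNA table holds 20624 genes with normalized values summing to 9628801 to 11582945 per library, and the MBD table holds 1000 windows of 100 bp with a score between 0 and 1. Animals are numbered 1 to 6 within each group as in the labels, and the same number denotes the same animal of that group in both assays. Sequencing depth is unknown for both assays.

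The first comparison asked whether prenatal BPA left a lasting difference in the RNA of adult fat. The genes with the smallest p that were lower in BPA included Bst1, a surface enzyme of the ADP-ribosyl cyclase family, at 66.3 ± 36.9 in BPA against 179.9 ± 82.6 in vehicle (SD, n = 6 each), a log2 fold of -1.50 with a 95% interval of -2.29 to -0.71. Msln (mesothelin, a surface protein of mesothelial cells) had a log2 fold of -1.52 (interval -2.40 to -0.63), the matrix metallopeptidase gene Mmp27 one of -1.12 (-1.72 to -0.52), and Cd163, the haemoglobin scavenger receptor of macrophages, one of -0.74 (-1.13 to -0.34). Dtd1, which encodes a D-aminoacyl-tRNA deacylase, was the remaining gene of this direction at -0.52 (-0.82 to -0.22). Those higher in BPA included the sodium pump subunit gene Atp1b2 at 0.39 (0.15 to 0.64), the zinc finger gene Zfp788 at 0.41 (0.15 to 0.67), Ppp4r1l at 0.47 (0.16 to 0.77) and Fam78b at 0.54 (0.19 to 0.89).

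None of these genes passed the test over all genes. With limma and Benjamini-Hochberg adjustment, 0 of 12528 genes were called in either direction, and the smallest adjusted p was 0.9997. An unadjusted p under 0.05 was found for 239 genes (117 higher and 122 lower in BPA), fewer than the 626 that independent genes without any difference would give. In 4 genes, Cd163, Zfp788, Prpf18 and Fam89a (the last 2 chosen after their values were seen), the 6 BPA values and the 6 vehicle values did not overlap, where chance gives 0.216% of genes, or 27.1. The half-width of the 95% interval was 0.34 on the log2 scale for the median gene.

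Among the 25 gene lists, mesothelial markers stood farthest from zero. All 9 measured members were lower in BPA, with a median log2 fold of -1.09. Over all genes 0 members passed, and 2 passed when adjusted over the list alone: Msln (limma adjusted p = 0.0226) and Lrrn4 (log2 fold -1.25, limma adjusted p = 0.0434). As a set the list was called lower by camera (adjusted p = 6.25e-08), with adjusted p = 0.475 under an estimated correlation. By animal, the list mean over all members in the table gave an exact permutation p of 0.13. For the other lists that camera called, this exact permutation p lay between 0.156 and 0.545. Among the vehicle animals, Msln reached 301.1 in animal 1 and 64.6 to 135.0 in the others. BPA animal 3 was the highest of its group, with a mean log2 value of 7.72 for the list against 4.62 to 6.59 in the other BPA animals, and vehicle animal 1 was at 7.55.

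Markers of macrophages and of inflammation were also lower in BPA by list. Of 22 macrophage genes 20 were lower, with a median log2 fold of -0.39 (camera adjusted p = 2.2e-07, and adjusted p = 0.475 with an estimated correlation). Over all genes 0 members passed, and Cd163 passed when adjusted over the list alone (limma adjusted p = 0.0321). Of 11 genes for inflammatory cytokines and acute phase proteins 10 were lower (median -0.60, camera adjusted p = 0.0431, and adjusted p = 0.555 with an estimated correlation), among them the chemokine genes Ccl7 (-0.70) and Cxcl10 (-0.60). Interferon response genes had a median of -0.23 with 14 of 18 members lower, including Bst2 at -0.67, Mx1 at -0.68 and Oasl2 at -0.65 (camera adjusted p = 0.00713, and adjusted p = 0.57 with an estimated correlation). Fibroblast and extracellular matrix genes were lower in 21 of 23 members (median -0.15, camera adjusted p = 0.000412, and adjusted p = 0.475 with an estimated correlation), with the gelatinase gene Mmp2 at -0.33, Col6a1 at -0.25 and Mmp14 at -0.36. No member of these last 3 lists passed over all genes or adjusted over the list alone. Without BPA animal 4 the interferon list had a median of -0.10 and was not called (camera adjusted p = 0.122), and the cytokine list lost its call without BPA animal 3, BPA animal 4, vehicle animal 4 or vehicle animal 5 (medians -0.51, -0.45, -0.65 and -0.56, camera adjusted p = 0.273, 0.114, 0.0611 and 0.0882) and under quantile normalization (0.0603). Without BPA animal 5 the cytokine list stayed called with a median of -0.40. Vehicle animal 3 was the highest of its group in all 4 lists, and without it the medians were -0.09 for macrophage, -0.09 for cytokines, -0.03 for interferon and -0.04 for matrix genes, and camera called none of the 4 (adjusted p = 0.106, 0.827, 0.801 and 0.0996).

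Lists called higher in BPA by camera were brown and beige fat, smooth muscle, endothelium, and immediate early and heat shock. All 10 measured genes of brown and beige fat were higher, with a median log2 fold of 0.35 (camera adjusted p = 0.00171), including Prdm16, a regulator of brown adipocyte fate, at 0.41, Cpt1b at 0.75 and Cox7a1 at 0.72. All 10 smooth muscle genes were higher as well (median 0.35, camera adjusted p = 0.00153), with Lmod1 at 0.63, Myh11 at 0.61 and Synpo2 at 0.28. Both calls rested on BPA animal 3: without it the medians were 0.11 and 0.14 (camera adjusted p = 0.266 and 0.41). Without BPA animal 1 the smooth muscle median was 0.55. Ucp1, the uncoupling protein of brown fat, chosen after its values were seen, was at 1463 in BPA animal 3 and at 39.4 or less in every other animal. Endothelial genes had a median of 0.10 with 13 of 15 higher (camera adjusted p = 0.0116), led by Egfl7 at 0.35, Robo4 at 0.27 and the von Willebrand factor gene Vwf at 0.33. Immediate early and heat shock genes had a median of 0.10 (camera adjusted p = 0.0394), with the AP-1 gene Jun at 0.26, Fosl1 at 0.67 and the phosphatase gene Dusp1 at 0.41. The endothelial call was lost without BPA animal 1, 2 or 4 or vehicle animal 6 (medians 0.06, 0.11, 0.07 and 0.07, camera adjusted p = 0.0781, 0.0579, 0.0963 and 0.262). The immediate early call was lost without BPA animal 3, 4 or 5 (medians 0.03, 0.08 and 0.07, camera adjusted p = 0.21, 0.0963 and 0.212) and without vehicle animal 1, 4, 5 or 6 (medians 0.15, 0.11, 0.08 and 0.06, camera adjusted p = 0.0525, 0.115, 0.0923 and 0.262). Without BPA animal 1 its median was 0.21. With an estimated correlation the adjusted p = 0.475 for each of these 4 lists, and no member passed over all genes or adjusted over the list alone.

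Erythroid genes, which mark blood in the tissue, were lower in all 4 measured members (median -0.51, camera adjusted p = 0.0144, and adjusted p = 0.475 with an estimated correlation). Alas2, the erythroid enzyme of haem synthesis, had a log2 fold of -0.47, and the beta-globin genes Hbb-b1 and Hbb-b2, near-identical copies with identical values here, one of -0.56. Camera counted these identical values as separate members, so its p at the preset correlation overstates the evidence for this list. No member passed over all genes or adjusted over the list alone, and the call was lost without BPA animal 1 or 3 or vehicle animal 1 or 5 (medians -0.46, -0.32, -0.42 and -0.42, camera adjusted p = 0.0781, 0.222, 0.0921 and 0.0641).

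Genes of the adipocyte itself did not separate the groups as lists. White adipocyte identity genes were higher in 12 and lower in 11 members, with a median log2 fold of 0.0089 (camera adjusted p = 0.775). The angiotensinogen gene Agt had a log2 fold of -0.54 (interval -1.12 to 0.05), Pparg, the master regulator of fat cell differentiation, 0.27 (-0.15 to 0.69), and Slc2a4, the insulin-responsive glucose transporter, 0.17 (-0.10 to 0.44). Fatty acid and triglyceride synthesis genes had a median of 0.05 (camera adjusted p = 0.193), with the lipogenic regulator Srebf1 at 0.25 (-0.01 to 0.52), Thrsp at 0.36 and Dgat2 at 0.24. Cholesterol synthesis genes had a median of 0.06 (camera adjusted p = 0.306), with Mvk at -0.33, Insig1 at 0.30 and Sc5d at 0.22. Medians were 0.011 for fatty acid oxidation (Hadhb at 0.32), 0.0019 for oxidative phosphorylation (Cycs at -0.50, Uqcrc1 at 0.13) and 0.04 for insulin signalling (Socs3 at -0.58, Tbc1d4 at 0.18), with camera adjusted p = 0.57, 0.72 and 0.432. The oxidative phosphorylation genes had a mean and a camera direction below zero. Each of these 6 medians takes the other sign without some single library, so none gives a direction. No member of these 6 lists passed over all genes or adjusted over the list alone. Single libraries moved some of these lists past the threshold, all of them higher in BPA: without BPA animal 5 the adipocyte, fatty acid synthesis and insulin lists (camera adjusted p = 0.0341, 0.0371 and 0.0371, medians 0.10, 0.08 and 0.07), without vehicle animal 1 or 4 the fatty acid synthesis list (0.039 and 0.00581, medians 0.12 and 0.15), and without vehicle animal 3 the cholesterol list (0.0433, median 0.12).

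Nuclear receptor and steroid genes had a median of -0.0031 but a mean and a camera direction above zero (camera adjusted p = 0.66), with the membrane estrogen receptor gene Gper at 0.44 (0.03 to 0.86), the 5-alpha-reductase gene Srd5a1 at 0.70 and Hsd11b1, which regenerates active glucocorticoid, at -0.28. Genes of the DNA methylation machinery had a median of 0.05 (camera adjusted p = 0.632), with Gadd45a at -0.24, Mbd1 at 0.16 and Mbd4 at 0.14. Imprinted genes had a median of 0.04 with 14 of 20 higher (camera adjusted p = 0.136), among them Airn at 0.48, Gnas at 0.19 and the growth factor gene Igf2 at 0.31. Circadian clock genes had a median of 0.08 (camera adjusted p = 0.157), with Nr1d2 at 0.31, Hlf at 0.24 and Per2 at 0.47. T and B lymphocyte genes had a median of -0.04, although their mean was above zero and their camera direction below it (camera adjusted p = 0.767), with the immunoglobulin joining chain gene Igj at 1.20. Skeletal muscle genes had a median of -0.12 over 4 measured members (camera adjusted p = 0.196), led by Mybpc2 at -1.76. The lymphocyte median was -0.25 without BPA animal 2 and 0.26 without vehicle animal 3, and the skeletal muscle median -0.24 without BPA animal 2 and 0.05 without BPA animal 5. Cell cycle genes had a median of -0.13 (camera adjusted p = 0.157), with Bub1b at -0.51, Cdc2a at -0.41 and Kif11 at -0.37. Without vehicle animal 3 the cell cycle median was 0.18 and camera called the list higher (adjusted p = 0.00424), while without vehicle animal 1 or 2 the medians were -0.26 and -0.24 and camera called it lower (adjusted p = 0.0175 and 0.036). Camera called the imprinted list higher without BPA animal 5 or vehicle animal 1 (adjusted p = 0.00621 and 0.039, medians 0.14 and 0.07) and the clock list without BPA animal 6 (adjusted p = 0.0458, median 0.21). Each of these 7 medians takes the other sign without some single library, so none gives a direction. No member of these 7 lists passed over all genes or adjusted over the list alone.

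**Figure D1:**
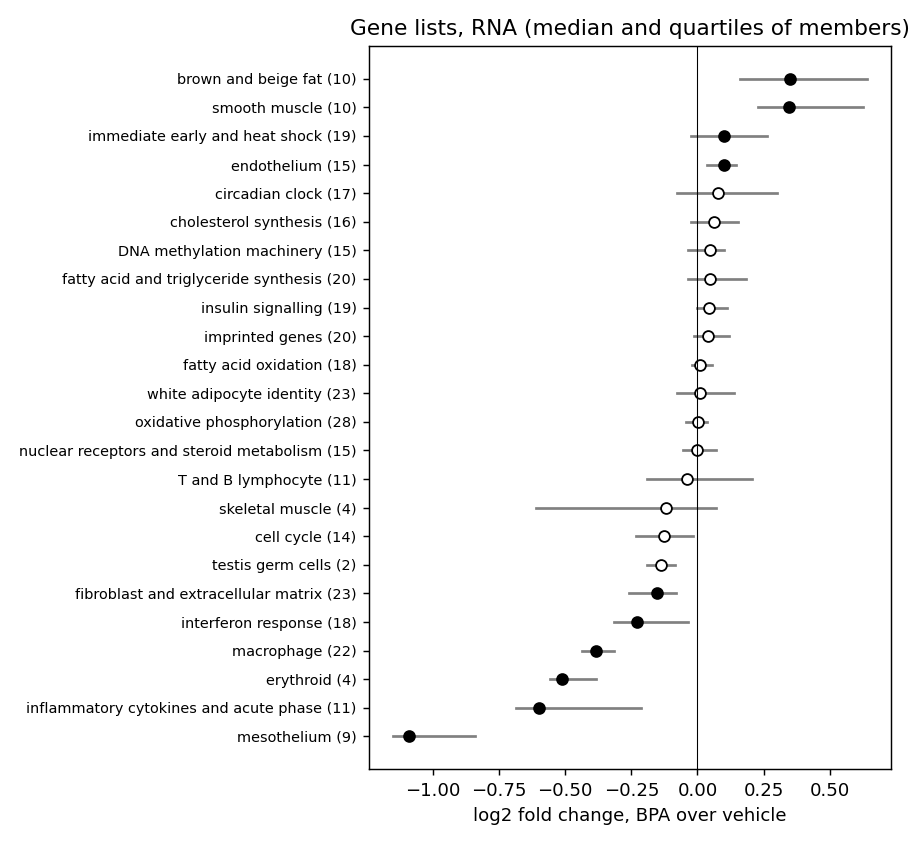
Points give the median log2 fold change (BPA over vehicle) of the measured members of each gene list, lines span the quartiles, and the number of measured members is in brackets. Filled points mark the 10 lists called by camera at the preset correlation; the mesothelium list lies lowest at -1.09, and none of the 10 was called with an estimated correlation.

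Several libraries carried transcripts of other tissues, in both exposure groups. The genes in this paragraph were chosen after their values were seen. Lrp2, an endocytic receptor of absorptive epithelia, was at 11906 in BPA animal 5, 6882 in vehicle animal 6 and 3303 in BPA animal 2, against 51.8 in BPA animal 6. Pax8, a transcription factor of duct and tubule epithelia, was at 662.3, 493.8 and 199.0 in those 3 animals and at 0.5 in BPA animal 1, and Foxj1, the regulator of motile cilia, at 136.2, 145.2 and 49.0 against 0.0 in BPA animal 1. The list means of duct epithelium markers were 5.13 ± 2.06 in BPA and 5.32 ± 1.56 in vehicle (SD, n = 6 each, exact permutation p = 0.872). The epididymal epithelium list had no member past the filter, and its genes Adam7 and Crisp1 were at 3280 and 1416 in vehicle animal 6 and at 333.4 and 255.4 in vehicle animal 4. Testis germ cell genes had 2 measured members, both lower in BPA, led by Gapdhs at -0.24 (camera adjusted p = 0.432), and over all 14 members the list means were 1.40 ± 0.43 in BPA and 2.46 ± 1.09 in vehicle (SD, n = 6 each, exact permutation p = 0.0628). Without the 3 libraries highest in duct epithelium markers, limma called 0 genes, with 449 at an unadjusted p under 0.05. In that fit the endothelial and immediate early lists were no longer called by camera (adjusted p = 0.0875 and 0.726), the erythroid list had a median of -0.92, and the adipocyte, fatty acid oxidation, insulin and imprinted lists were called higher (adjusted p = 0.0396, 0.0374, 0.0138 and 0.00562).

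**Figure D2:**
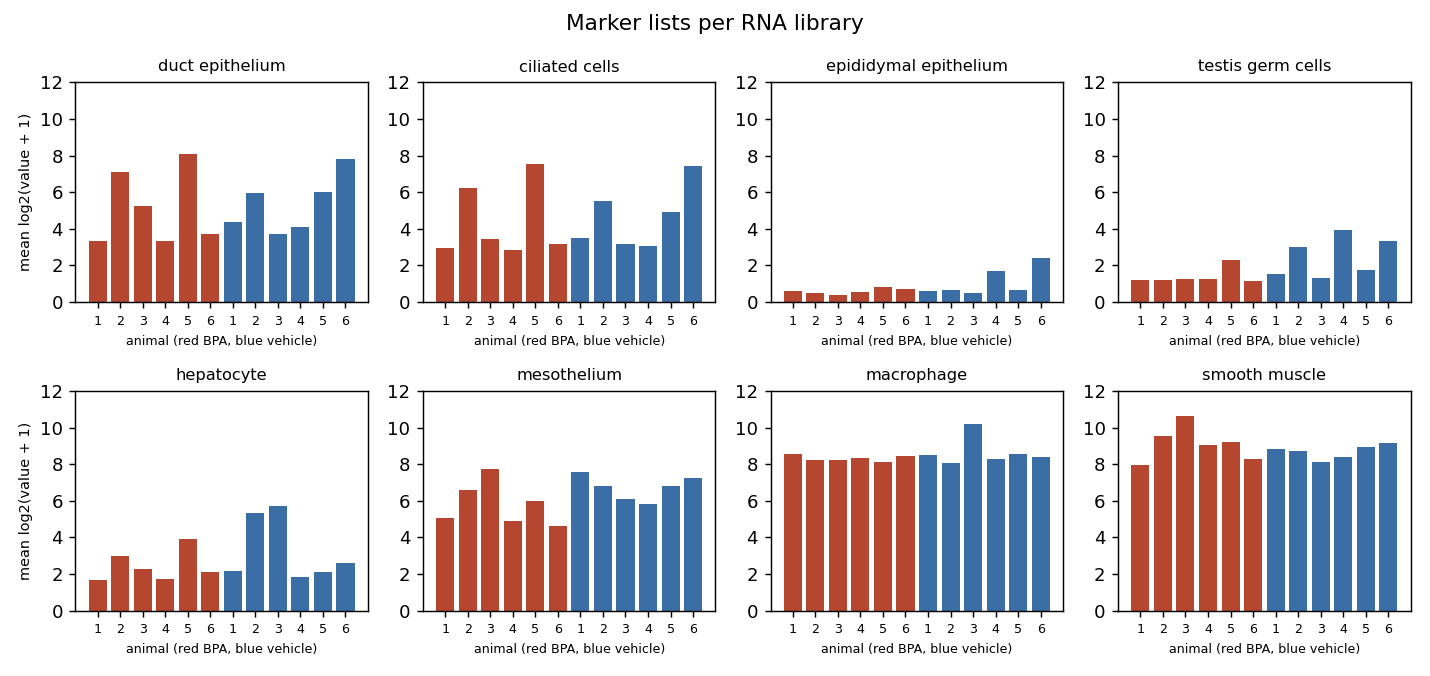
Bars give the mean log2(value + 1) of a marker list in each RNA library (red BPA, blue vehicle, numbered by animal). Duct epithelium and ciliated cell markers are highest in BPA animals 2 and 5 and vehicle animal 6, macrophage markers in vehicle animal 3 (10.2), and smooth muscle markers in BPA animal 3 (10.6).

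Fggy, which encodes a carbohydrate kinase and is the gene the study is known for, was examined on its own. Its value lay between 534.6 and 701.4 in the 6 BPA animals, with a mean of 621.9 ± 69.2 (SD, n = 6). The vehicle animals fell into a low and a high set: animals 2, 3 and 5 were at 162.3, 195.6 and 153.5, and animals 1, 4 and 6 at 648.6, 605.5 and 591.4, giving a mean of 392.8 ± 244.7 (SD, n = 6). The log2 fold of BPA over vehicle was 0.94 with a 95% interval of 0.14 to 1.73. Limma gave an unadjusted p of 0.0242 for this gene alone and an adjusted p of 0.9997 over all genes. The exact permutation test of the difference in means gave a two-sided p of 0.0844. With all animals included, Fggy was therefore not called by either test. Leaving out vehicle animal 1, 4 or 6 gave log2 folds of 1.14, 1.12 and 1.11 with exact p of 0.0216, 0.0303 and 0.0368. These are the vehicle animals with high Fggy, so leaving out any of them lowers the vehicle mean. Leaving out any other single animal gave an exact p of 0.0909 to 0.134. An exact permutation test of the spread, chosen after seeing the data, gave p = 0.139. Any assignment that keeps the low animals together in the same group gives a similar difference in spread. This p could therefore hardly be small, and it does not show whether the split follows exposure.

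**Figure D3:**
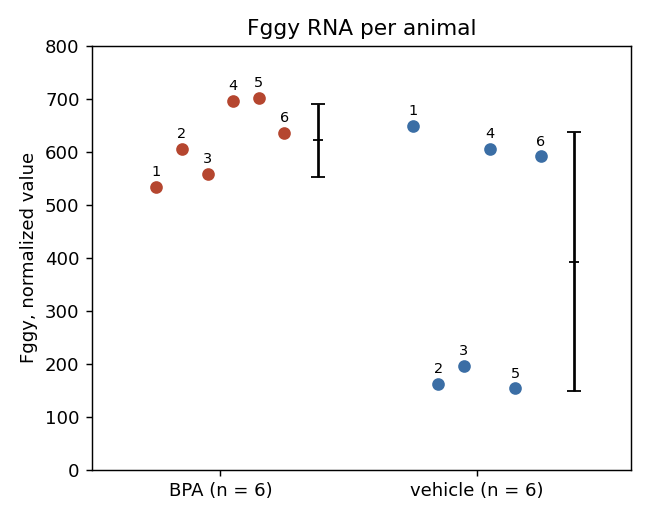
Points show the normalized Fggy value of each animal, numbered within its group, and the bars beside them give mean and SD (n = 6 each). The BPA animals lie between 534.6 and 701.4, while vehicle animals 2, 3 and 5 lie at 195.6 or lower and vehicle animals 1, 4 and 6 at 591.4 or higher.

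The authors' own comparison was a different one. A header line in the authors' deposited table marks vehicle animals 2, 3 and 5 as low Fggy and the other vehicle animals as high Fggy. The p-values in the authors' deposited table were reproduced to within 8.4e-16 for 523 genes by an equal-variance comparison of those 3 animals with the other 9, BPA animals included. Because the 3 animals were grouped by their Fggy level, the result for Fggy itself is not independent evidence. In the authors' deposited table, 9522 genes have a maximum of at least 100, 524 of these (5.5%) have p under 0.05, and 42 also have a fold of at least 2. After Benjamini-Hochberg adjustment of the 9522 p-values from the authors' deposited table, 2 stayed under 0.05, those of Fggy (adjusted 0.0013) and Darc (0.0388, chosen after its value was seen).

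Of the 42 genes in the authors' deposited table, 30 were higher in the low-Fggy animals. The largest folds in the authors' deposited table were those of genes known from hepatocytes and plasma, Apob (9.02), Pzp (7.35), Fga (6.09) and Alb (3.29), together with Dhrs9 (3.83), the chemokine gene Ccl6 (3.73), Ms4a6d (3.24) and Pkib (3.07). For 27 of the 30 the highest of the 3 low-Fggy animals was vehicle animal 3, which for 24 of them exceeded the next of the 3 more than 2-fold. The 12 genes lower in the low-Fggy animals were led in the authors' deposited table by Fggy (3.55), ORF63 (3.4), the kinase gene Adrbk2 (3.0), A930005H10Rik (2.97), Akr1e1 (2.81), 6720401G13Rik (2.62), D3Ertd751e (2.59) and Eppk1 (2.5). For all 231 genes lower in that group, the fold in the authors' deposited table equalled the value of BPA animal 2 alone divided by the mean of the 3 animals (to within 0.1%). With the mean of all 9 other animals, 39 genes reach a fold of 2, and ORF63 has a ratio of 2.1. None of the 42 was called in the comparison of BPA with vehicle, where 10 of them had an unadjusted p under 0.05 by limma. Over all tested genes that share was 1.91%. The 42 were chosen on these same libraries, with the low-Fggy animals part of the vehicle group, so the 10 are not independent evidence of a BPA difference.

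The MBD comparison asked whether prenatal BPA left a difference in DNA methylation at the listed windows. The 6 windows with the smallest p are given with their mm9 positions. On chromosome 13, the window from 99816801 to 99816900 scored 0.31 ± 0.24 in BPA and 0 in all 6 vehicle libraries, and the window from 115949901 to 115950000 scored 0.51 ± 0.08 against 0.21 ± 0.23 (SD, n = 6 each). The windows at 61579101 to 61579200 on chromosome 18, 25803901 to 25804000 on chromosome 19 and 11394201 to 11394300 on chromosome 14 were higher in BPA by 0.34, 0.27 and 0.34. The window at 62218401 to 62218500 on chromosome 4 was the one higher in vehicle, at 0.48 ± 0.05 against 0.17 ± 0.27 (SD, n = 6 each). None passed adjustment (limma adjusted p = 1.0 for each of the 6).

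Over the 1000 windows limma called 0, with 14 at an unadjusted p under 0.05 (12 higher and 2 lower in BPA) where 50 are expected without any difference. In 0 windows did the 6 BPA and the 6 vehicle scores not overlap, where chance gives 2.16. By mean score 646 windows were higher and 337 lower in BPA. This split followed the scale of single libraries: BPA animal 1 had a median score of 0.70 and was the highest of the 12 in 913 windows, and BPA animal 3 had a median of 0.43 with 33.2% of windows at 0, while the vehicle medians lay between 0.49 and 0.52. Without BPA animal 1 the split was 331 higher and 665 lower, without BPA animals 1 and 3 it was 512 and 479, and after rescaling by the median ratio it was 482 and 518. Limma called 0 windows in each of these settings, with 34, 37 and 29 windows at an unadjusted p under 0.05.

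**Figure D4:**
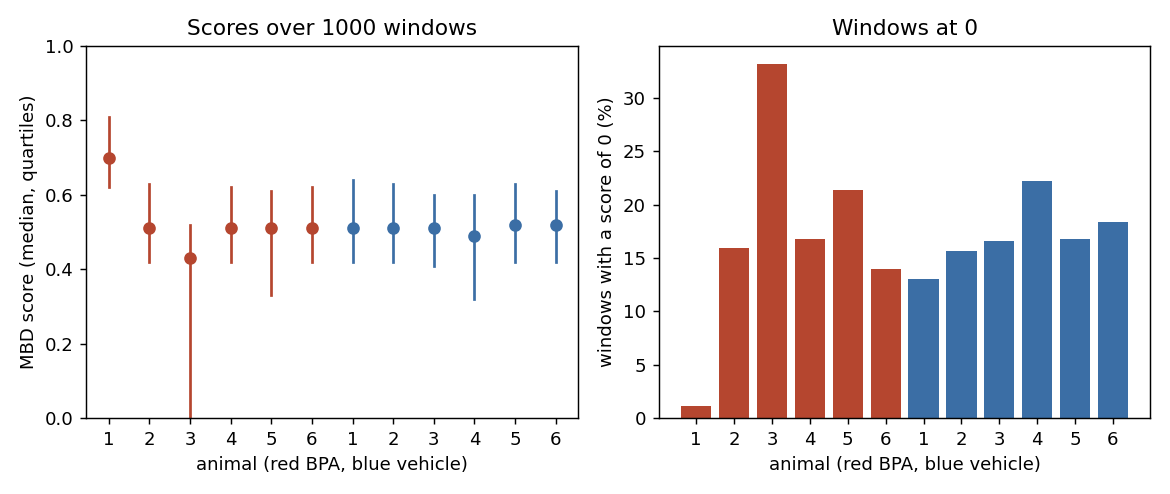
Left, the median score (points) and quartiles (lines) of each MBD library over the windows; right, the percent of windows at a score of 0 (red BPA, blue vehicle, numbered by animal). BPA animal 1 has a median of 0.70 with 1.1% of windows at 0, and BPA animal 3 a median of 0.43 with 33.2% at 0, while the vehicle libraries have 13.0% to 22.2% at 0.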

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

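All tests of explanations for the MBD library of BPA animal 1, for the duct and cilia transcripts and for low Fggy (adipocyte share, library scaling and genes with the same split) were chosen after the results had been seen. An extreme animal was looked for in 86 groups of 6 values, and 10 were found whose gap to the nearest animal, as a share of the group's range, passed Dixon's critical value. Chance gives about 1 in 20 groups.

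Vehicle animal 3 stood apart in 6 lists. Its mean log2 values were the highest of its group for macrophage (10.2, next 8.57), inflammatory cytokine (6.58, next 4.88), interferon (7.66, next 6.64), matrix (11.8, next 11.4) and cell cycle genes (6.41, next 4.63), and the lowest for imprinted genes (7.16, next 7.51). Among the BPA animals, germ cell genes were highest in animal 5 at 2.28 (next 1.27), below vehicle animals 2, 4 and 6. Msln was at 301.1 in vehicle animal 1 and at 135.0 in the next. The MBD median of vehicle animal 4 was the lowest of its group at 0.49.

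The MBD median of BPA animal 1 was 0.70, with the next BPA library at 0.51. A rise shared by all BPA animals is argued against by the other 5 BPA libraries, whose highest median, 0.51, did not exceed the highest vehicle median of 0.52 (331 of 1000 windows were higher in BPA without BPA animal 1, and 512 without BPA animals 1 and 3), while a response of this animal alone was not tested. A deeper library or a larger scale of its own would draw on the other libraries by their reliability, yet the regression weights of vehicle animals 2, 4 and 6 and BPA animals 5 and 6, picked in odd windows, were 0.099 to 0.138 in even windows against 0.012 to 0.059 for the other 6, a gap of 0.0396 (SE 0.015). The correlation of those 5 libraries with one another was lower by 0.0134 than with the other 6 (difference -0.0134). Because weights in a joint regression favour libraries that overlap little, this cannot decide whether a batch was shared with them. Scores were then compared in the 11 windows where BPA animal 1 is at 0, none of them used to pick these libraries. Those 5 libraries had 0 of 55 scores above 0 and the other 6 had 25 of 66 (Fisher's exact p = 2.31e-08, windows and libraries taken as independent, with 0 above 0 also in BPA animal 3). The 5 were picked for their weight on BPA animal 1 and correlate most with it (r = 0.742 to 0.765, against 0.656 to 0.703). Zeros shared with it could also follow from that similarity. Another candidate explanation that stays open is that reads of several libraries of both exposure groups were merged into this column.

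Duct and cilia transcripts in some RNA libraries formed the first principal component (43.6% of the variance, exact permutation p = 0.996 for a difference between the groups). BPA exposure as the cause is argued against by vehicle animal 6, which exceeded 5 of the 6 BPA animals in the duct list (exact permutation p = 0.872 between the groups). Kidney tissue as the main source is argued against by its abundant transcripts Kap, Umod and Slc34a1, at 0.9, 3.0 and 5.9 or less in the 3 highest libraries, although the kidney tubule list was also highest in these 3 (1.55 to 1.82, next 1.46), and epididymal epithelium by its list, which in BPA animal 2 lay at -0.1 relative to the median library while vehicle animal 6 lay at 1.81. The duct list, most of whose 14 genes had been seen, and 7 ciliated cell genes whose own values had not been seen (the correlation of the whole ciliated list had) were high in the same libraries (Pearson r = 0.967, Spearman rho = 0.965 over 12 libraries, permutation p = 1e-05 for each, the smallest that 100000 resamples give, and r = 0.931 without the 2 farthest libraries). Epithelium of a neighbouring organ in the dissected piece may therefore be the source, with Lrp2 at 11906 and Dnahc5 at 981.6 in BPA animal 5.

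Low Fggy in vehicle animals 2, 3 and 5 was weighed against the makeup of the tissue. A lower share of adipocytes is argued against by the adipocyte list, whose lowest library, BPA animal 5, lay at -0.538 relative to the median library, while the 3 low-Fggy animals lay at -0.06, -0.20 and 0.10. The scaling of the libraries is argued against by the median gene, which moved by at most 0.0265 on the log2 scale in any library. A programme shared with many genes stays open: 3 genes (Fggy, Dnajb13 and Ear11, chosen after their values were seen) split the vehicle animals into the same 3 and 3 with a gap of at least 1 on the log2 scale and at least 2 cluster widths, but only 7 genes reach that bar for any split, so smaller shared differences would be missed. The difference between the exposure groups (exact permutation p = 0.0844) and an inherited difference between outbred animals were not excluded, the latter being untested.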

How the results depend on the processing

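Settings marked here as added were chosen after seeing the data. The count of genes called between BPA and vehicle was 0 under every RNA setting run, including a two-sample test without moderation, with 150 to 497 genes at an unadjusted p under 0.05. The smallest limma adjusted p was 0.350 without BPA animal 5 and 0.563 without BPA animal 3. The number of lists called by camera was 10 as reported, 0 with an estimated correlation, 0 with fry, and 5 to 13 when 1 library was left out. It was lowest without BPA animal 3 (5) and next without BPA animal 4 (6), and 12 and 9 in the added fits without the 3 libraries highest in duct markers and with those markers as a covariate. With the covariate the immediate early and heat shock list lost its call (camera adjusted p = 0.0606). The mesothelium list was called lower by camera in every fit at the preset correlation, with medians of -1.40 to -0.79. The log2 fold of Fggy was 0.72 to 1.14 when 1 library was left out, and its exact permutation p passed 0.05 without vehicle animal 1, 4 or 6. Animals 1, 4 and 6 are the vehicle animals with high Fggy, so leaving out 1 of them lowers the vehicle mean. Fewer animals are compared in these fits. The number of MBD windows higher in BPA was 646 as reported, 482 after rescaling by the median ratio, 494 after the added quantile normalization, 483 after the added subtraction of library medians, and 331 to 806 when 1 library was left out (331 without BPA animal 1 and 806 without BPA animal 3). It was 512 in the added fit without both, and 480 when group medians replaced means. The count of MBD windows called was 0 in every setting, the added log2(score + 0.1) included, with 3 to 37 at an unadjusted p under 0.05. The camera direction of 9 uncalled lists turned in some fit. With 1 library left out the medians ran from -0.07 to 0.10 for adipocyte, -0.041 to 0.066 for fatty acid oxidation, -0.011 to 0.093 for insulin, -0.047 to 0.074 for oxidative phosphorylation, -0.036 to 0.050 for nuclear receptors, -0.25 to 0.26 for lymphocyte and -0.26 to 0.18 for cell cycle genes. Lymphocyte genes also turned under quantile normalization (0.0051) and with the replicate block (-0.039), cholesterol (-0.049) and germ cell genes (-0.022) in the added fit without the 3 libraries, and adipocyte genes with the added covariate (-0.00073). None of the 75 genes picked by the naming rule in the RNA comparison changed direction or passed the threshold in 1781 refitted values.

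Replicate numbers follow the order of animal identifiers and did not pair the animals: the correlation of same-numbered deviations ran from -0.569 to 0.398 for RNA and from -0.0909 to 0.0127 for MBD, and 1 of 6 BPA animals correlated best with its own number in RNA and 0 in MBD. With the replicate number as a block limma called 0 genes (226 at an unadjusted p under 0.05) and 0 windows, and camera called 10 lists. The Fggy log2 fold in that setting was 0.94 (exact permutation p = 0.125).

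Other MBD pseudocounts, a stricter threshold of the authors for windows, a count model for RNA, and all settings of the methylation against RNA comparison were not run, because the score has no pseudocount, the MBD table gives no p, the RNA values are not counts, and the windows were not assigned to genes. Depth is unknown for both assays.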

Other observations

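The marker lists named here, the spread test of Fggy and the reading of single libraries were chosen after the results had been seen, while the counts over other splits of the libraries were fixed before their results were seen. Liver-type transcripts were found in vehicle animals 2 and 3, in genes chosen after their values were seen. Alb was at 482.6 and 422.3 in these animals and at 138.5 or less in the other 10, and Apob, the structural protein of lipoproteins, was at 161.7 and 249.4 against 47.5 or less. The hepatocyte list means were 5.32 and 5.74 in these animals and 1.65 to 3.90 in the others, with group means of 2.44 ± 0.86 in BPA and 3.30 ± 1.75 in vehicle (SD, n = 6 each, exact permutation p = 0.299). Kidney tubule genes were low in every library, with list means of 0.98 to 1.82.

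Vehicle animal 3 carried high values of acute phase genes. Saa3, a serum amyloid gene, was at 1816 in this animal and at 446.1 or less in the others, and this animal alone lay at 57.8 on the second principal component, with the others between -13.7 and 6.3 (12.7% of the variance). Lcn2 was not specific to it, at 1563 there and at 3063 in BPA animal 5. BPA animal 3 lay apart on the third component at 41.8 (9.51% of the variance), with Upk1b at 848.3 and Ucp1 at 1463.

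How far chance groupings reach was counted over 100 of the 462 ways to split the 12 libraries into 6 and 6. In each set of 100 splits the real split is 1 of the 100 and is included in the count. With 0 genes called between the exposure groups all 100 splits reach the real count, so this count says nothing about chance (highest other 47). For genes at an unadjusted p under 0.05, 93 splits gave as many as the 239 of BPA against vehicle, so chance could not be excluded. The highest other split had 1763, several times the real count, which points to a structure of the samples whose origin was not tested. For lists called by camera, 30 splits gave as many as 10 (median of the other splits 8, highest other 14), so chance could not be excluded. For the mesothelium list 6 splits gave a camera p as small (-log10 p of 8.58, highest other 12.0), so chance could not be excluded there either. Mesothelium had the smallest camera p of the lists and was compared only with the same list in other splits. The 6 is therefore a lower bound for splits in which any list goes as far. With 0 MBD windows called all 100 splits reach the real count as well (highest other 1), which says nothing about chance. For windows at an unadjusted p under 0.05, all 100 splits gave at least the real 14 (median of the other splits 38, highest other 123). BPA animals 1 and 3, with median scores of 0.70 and 0.43, lie in the same group of the real split. Without BPA animal 1 the count was 34, so the 14 says little about chance or about a BPA difference. For the count in the authors' deposited table, 26 of 100 drawn splits into 3 and 9 libraries (of 220) gave as many as 524 genes at p under 0.05, with 1703 in the highest other, so chance could not be excluded for that list as a whole.

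The spread of Fggy was examined because its vehicle values had been seen to split. By limma on the absolute deviation from each group's median, a test chosen after seeing the data, Fggy ranked 1 of 12528 genes for a difference in spread between the groups, with 0 genes past adjustment (limma adjusted p = 0.999 for Fggy) and 309 at an unadjusted p under 0.05. In 56 of 100 splits of the libraries some gene had a p as small (-log10 p of 2.81, highest other 5.83), so chance could not be excluded. By the mean difference Fggy ranked 89.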
